A study of Mus musculus with 10 samples.

How the data were processed

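The series measured poly(A)-selected RNA of GFP+ splenocytes from secondary transplant recipients with AML, 5 C57BL/6J and 5 Rag2-/-γc-/- mice, in NEBNext Ultra libraries sequenced as single reads on a NextSeq instrument, per the labels' protocols. The authors deposited a table of expected counts per Ensembl gene, with gene symbols and positions. Cutadapt 1.11, STAR 2.5.2a, RSEM 1.2.30 and edgeR are named, per the submitters' processing notes, together with build GRCm38; the role of each tool, the filters and the annotation release are not given in the sources used here. Expected counts are estimates in which reads that fit several genes are divided between them, so values of close paralogs depend on that division. The kit as named carries no statement on strand, so reads of overlapping and antisense genes may not be told apart.

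Libraries were assigned to recipient groups from their titles and the labels, and each column of the table carried the title of its library. The title numbers differ between the groups, and the labels give no batch, sex or primary donor, so no block could be fitted. The table lists 38215 genes. Of these, 36429 (95.3%) were found by identifier in GENCODE M21 on GRCm38, and 99.7% of those overlapped the position given there. Totals were 28157745 to 62461126 expected counts per library, and 15.3 to 17.3% of a library's values over all listed genes were not whole (any remainder above 0), so they were rounded to whole numbers before the count tests. Mitochondrial genes took 1.34% of C57BL/6J library 1 and 2.91 to 4.00% of the other 9. No pair of libraries within a group agreed within sampling noise (chi-square over its degrees of freedom 8.13 to 188 in 20 pairs), so all 10 were counted as separate.

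The main test was the quasi-likelihood F test of edgeR 4.0.16 (R 4.3.3) on rounded counts with TMM normalisation, the filterByExpr filter (minimum count 10, minimum total 15), a group term alone and Benjamini-Hochberg adjustment over 13966 genes with a threshold of 0.05. Log2 fold changes are C57BL/6J minus Rag2-/-γc-/-; their standard errors were taken as the unshrunken coefficient divided by the square root of F. CPM values are TMM-scaled and were computed from the rounded expected counts. Where a group had no counts in any library, a lower bound against a floor of 3 counts over the group replaces the fitted fold change, and where it had 1 to 3 counts, the ratio of summed counts is given with an exact 95% binomial interval; such bounds and intervals cover counting error only.

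The 30 gene lists, with 855 entries, were written before the data were examined; 844 entries were matched, 23 of them through the symbol that GENCODE M21 gives for the identifier. Lists with at least 5 tested members (29 of 30) were compared with all other genes by camera in limma 3.58.1 on log2 CPM (prior count 2) with a preset correlation of 0.01, adjusted over the 29 lists. With an estimated correlation camera called none of them (3 had an unadjusted p under 0.05), and fry, which asks whether a list's genes move one way on balance, called 9. Summed CPM of 8 lists of other cell types were compared by exact permutation over all 252 assignments of the libraries, two-sided, with adjustment over the 8 lists.

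Genes were named by a rule fixed before the data were examined: the 12 with the highest and the 12 with the lowest log2 fold change among genes past the threshold with a mean of at least 5 CPM and no overlap between groups, leaving out predicted genes; up to 4 members of each list with the smallest adjusted p, or the 1 with the smallest p where none passed; and 14 fixed genes, among them Rag2, Il2rg, Nras, Runx1, Runx1t1, B2m, H2-K1, H2-D1, Cd274, Cd80, Cd86, Ciita and Irf1. Some genes that this rule names are not reported here. The dendritic, granulocytic, stem and monocytic genes whose levels over all libraries are given beside these were picked after their values were seen.

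Tests on simulated data used counts drawn for the 13966 tested genes from the means and library sizes of this comparison, with 200 genes changed in each of 5 sets. The edgeR test recovered 24.5% of the genes changed 1.5-fold, 66.3% of those changed 2-fold and 89.4% of those changed 4-fold, with 4.5% false calls. Camera called 5 of 5 lists of 30 genes shifted 2-fold and 0 of 145 unshifted ones. Each simulated gene was drawn independently of the others, so these list results do not cover lists of correlated genes. In the data the estimated correlation within a list reached 0.8 (cell cycle). Alternatives fixed before the data were examined were other normalisations (RLE, upper quartile), DESeq2 1.42.0, limma-voom with and without sample quality weights, no and stricter count filters (1 CPM in 5 libraries), robust dispersion estimation, a test against a 1.5-fold change, 1 surrogate variable (sva 3.50.0) and leaving out each library in turn. Leaving out Rag2-/-γc-/- libraries 10 and 11, or 7, 8 and 9, was added after the data were examined. Figures were drawn with matplotlib.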

Results

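Gene expression was measured by RNA-seq in acute myeloid leukaemia (AML) cells of mice. The leukaemia had been started with retroviral AML1-ETO, a fusion of the transcription factor genes Runx1 and Runx1t1, and a mutant Nras oncogene, with GFP as the marker of transduced cells. Primary leukaemias had grown in Rag2-/-γc-/- mice, which lack T, B and NK cells. Their GFP+ spleen cells had been passed on to a second set of recipients, which were either immunocompetent C57BL/6J mice or again Rag2-/-γc-/- mice. The 10 libraries came from GFP+ splenocytes of 5 C57BL/6J recipients (numbered 1, 3, 4, 5 and 6 in the labels) and 5 Rag2-/-γc-/- recipients (numbered 7 to 11). How many primary leukaemias supplied these recipients is not stated in the labels, so p-values measure the spread between recipients and may not cover differences between primary leukaemias. Expected counts summed to 32703932 to 44097690 per library in the C57BL/6J group and 28157745 to 62461126 in the Rag2-/-γc-/- group, and 13966 of 38215 listed genes had enough counts to be tested.

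Several genes of antigen-presenting cells were abundant in all 10 libraries. Wdfy4, which is needed for cross-presentation by dendritic cells, averaged 1950 ± 180 CPM (SD, n = 10 libraries), and the chemokine receptor gene Xcr1 averaged 379 ± 106 CPM. Clec9a, another surface marker of cross-presenting dendritic cells, ranged from 48.0 to 336 CPM, and Irf8, a transcription factor of monocytes and dendritic cells, averaged 1650 ± 468 CPM. Of the 14 matched genes for MHC class II presentation, 11 averaged over 50 CPM. The median of the 29 matched granulocytic genes was 0.57 CPM, with Mmp9 (8660 ± 1700 CPM) and Itgam (760 ± 255 CPM) as the exceptions over 50 CPM. Among stem and progenitor genes, 18 of 33 averaged under 1 CPM, whereas Cd34 averaged 232 ± 136 CPM. Runx1t1, the mouse counterpart of the ETO part of the fusion, had no counts in 9 libraries and 0.0253 CPM in Rag2-/-γc-/- library 11. Reads from the introduced fusion itself were not analysed here.

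The comparison of C57BL/6J with Rag2-/-γc-/- recipients asked how growth under an intact immune system, termed immunoediting in the study's design, affected the transcriptome of the leukaemia. In cells from C57BL/6J recipients 464 genes were higher and 624 were lower (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05), 247 and 328 of them by more than 2-fold. The 5 values of each group did not overlap in 1187 of the tested genes (8.50%, against 0.79% by chance). The strongest increase among named genes averaging at least 5 CPM was in Iigp1, an interferon-inducible GTPase of cell-autonomous immunity, which reached 17.7 ± 4.40 CPM (SD, n = 5) against 0.51 ± 0.401 CPM. The strongest decrease among them was in Atrnl1, an attractin-like membrane protein gene, at 0.479 ± 0.211 CPM against 59.0 ± 16.4 CPM. The count of calls depended on the libraries: there were 275 higher and 304 lower genes without C57BL/6J library 6, 301 and 310 without Rag2-/-γc-/- library 9, and 1076 and 1323 without Rag2-/-γc-/- library 10. There were 356 and 415 without C57BL/6J library 3, 398 and 371 without C57BL/6J library 5, 334 and 383 without Rag2-/-γc-/- library 7, and 319 and 317 without Rag2-/-γc-/- library 8. DESeq2 called 803 and 1155 genes, limma-voom with sample quality weights 3306 and 3217, and a test against a 1.5-fold change 126 and 119.

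**Figure D1:**
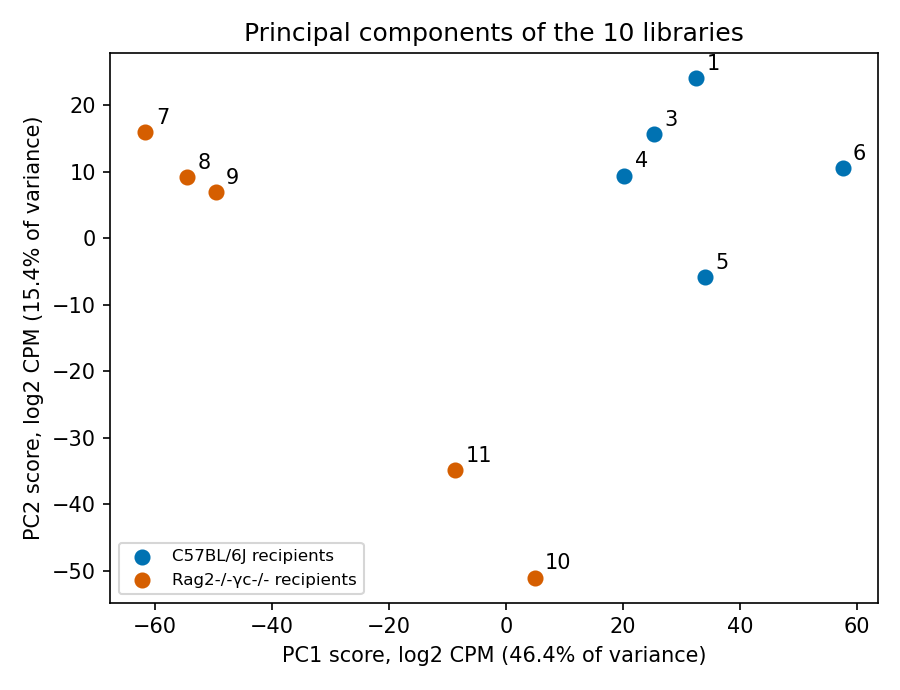
Scores of the 10 libraries on the first 2 principal components of log2 CPM (axes in score units, with the share of variance), one point per library and coloured by recipient type. C57BL/6J libraries lie between 20.2 and 57.5 on the first component, Rag2-/-γc-/- libraries 7, 8 and 9 between -61.6 and -49.6, and libraries 10 and 11 at 4.9 and -8.7.

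The Rag2-/-γc-/- group was not uniform. On the first principal component, which held 46.4% of the variance, libraries 7, 8 and 9 scored -61.6, -54.4 and -49.6, while libraries 10 and 11 scored 4.9 and -8.7, between these and the C57BL/6J libraries at 20.2 to 57.5. On the second component (15.4%) libraries 10 and 11, at -51.0 and -34.9, lay apart from libraries 7, 8 and 9 (6.9 to 16) and from the C57BL/6J libraries (-5.8 to 24.1). The C57BL/6J group was not uniform either. On the third component (14%) C57BL/6J library 1 scored -57.4, against 11.5 to 20.6 in C57BL/6J libraries 3, 4, 5 and 6. It also had the lowest sample quality weight in limma-voom (0.26). Rag2-/-γc-/- libraries 10 and 11 had the next lowest weights, 0.30 and 0.34, against 0.70, 2.46 and 3.53 in libraries 7, 8 and 9. Without libraries 10 and 11 the edgeR test called 2786 genes higher and 2518 lower. Without libraries 7, 8 and 9, which leaves 5 libraries against 2, it called 148 and 127. Both alternatives were added after the data were examined. In common, 117 higher and 92 lower genes were called with all libraries and in both of these subsets. Of the 110 named genes past the threshold, 82 remained past it when any 1 library was left out, and 73 lost it without libraries 7, 8 and 9.

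The 12 genes named for the largest increases, all averaging at least 5 CPM, were led by an interferon-inducible GTPase gene. Iigp1 (chromosome 18, 60376029 to 60392627, GRCm38, protein-coding) rose by 5.10 ± 0.44 on the log2 scale (SE; edgeR adjusted p = 8.75e-05). Cyp26b1 (chromosome 6, 84571414 to 84593908), which degrades retinoic acid, rose by 3.87 ± 0.52 (edgeR adjusted p = 0.00122), and Aldh1a2 (chromosome 9, 71215789 to 71296243), which makes retinoic acid, by 3.11 ± 0.30 (edgeR adjusted p = 0.000217). Aldh1a2 was the more abundant of this pair, at 117 ± 25.7 CPM against 13.6 ± 5.57 CPM (SD, n = 5 each). The G protein subunit gene Gnb4 rose 13.9-fold, the uridine phosphorylase gene Upp1 11.3-fold and the heparanase gene Hpse 9.35-fold. The other 6 were Mgl2, a C-type lectin gene (6.89-fold), Rtn4rl1 (6.26-fold), Plaa (5.34-fold), Fndc5 (5.23-fold), Fam176a (4.91-fold) and the developmental transcription factor gene Pax3 (4.62-fold). The increase of Fndc5 rested partly on C57BL/6J library 6, at 29 CPM against 5.77 to 8.74 in the other 4, and its log2 fold change was 1.73 without that library and 2.39 with it. Leaving out Rag2-/-γc-/- library 8 moved the log2 fold change of Iigp1 to 5.69. Without Rag2-/-γc-/- libraries 7, 8 and 9, Plaa (adjusted p = 0.071) and Fndc5 (adjusted p = 0.23) lost their edgeR calls and the log2 fold changes of Iigp1 and Upp1 were 5.77 and 2.80. That of Upp1 was 4.25 without libraries 10 and 11, against 3.49 with all.

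The 12 genes named for the largest decreases, all averaging at least 5 CPM, were led by Atrnl1. It (chromosome 19, 57611034 to 58133338, GRCm38, protein-coding) fell by 6.95 ± 0.32 on the log2 scale (SE; edgeR adjusted p = 1.46e-06), with 37.7 to 73.8 CPM in the Rag2-/-γc-/- libraries and 0.252 to 0.794 CPM in the C57BL/6J libraries. Alox5, the 5-lipoxygenase of leukotriene synthesis, was 12.4-fold higher in Rag2-/-γc-/- recipients and Hpgd, which inactivates prostaglandins, 20.1-fold. Pip5k1b was 25.3-fold higher in Rag2-/-γc-/- recipients, the transporter gene Slco2b1 11.4-fold, the Notch coactivator gene Maml3 11.3-fold, the transferrin gene Trf 10.7-fold, the scavenger receptor gene Stab1 9.70-fold, the adhesion molecule gene Pecam1 9.41-fold, the sorting receptor gene Sorl1 9.05-fold and the serine protease gene Prss16 7.24-fold. Nlrp14 was 36.4-fold higher, with 43.5 CPM in Rag2-/-γc-/- library 10 and 3.70 to 11.5 CPM in the other 4. Without library 10 its log2 fold change was -4.23, and without 10 and 11 -3.96, against -5.19 with all. Without C57BL/6J library 5 the log2 fold change of Pip5k1b was -5.53 and that of Prss16 -3.80, and without C57BL/6J library 1 that of Pecam1 was -3.83. Stab1 lost its call (edgeR adjusted p up to 0.053) without C57BL/6J library 3 or 5 or Rag2-/-γc-/- library 8. Without Rag2-/-γc-/- libraries 7, 8 and 9 the log2 fold changes were -1.94 for Alox5, -1.97 for Slco2b1, -2.79 for Stab1, -2.42 for Sorl1 and -2.01 for Prss16, none past the threshold. They were -6.08 for Nlrp14, -2.88 for Maml3 and -2.42 for Trf, all past it.

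**Figure D2:**
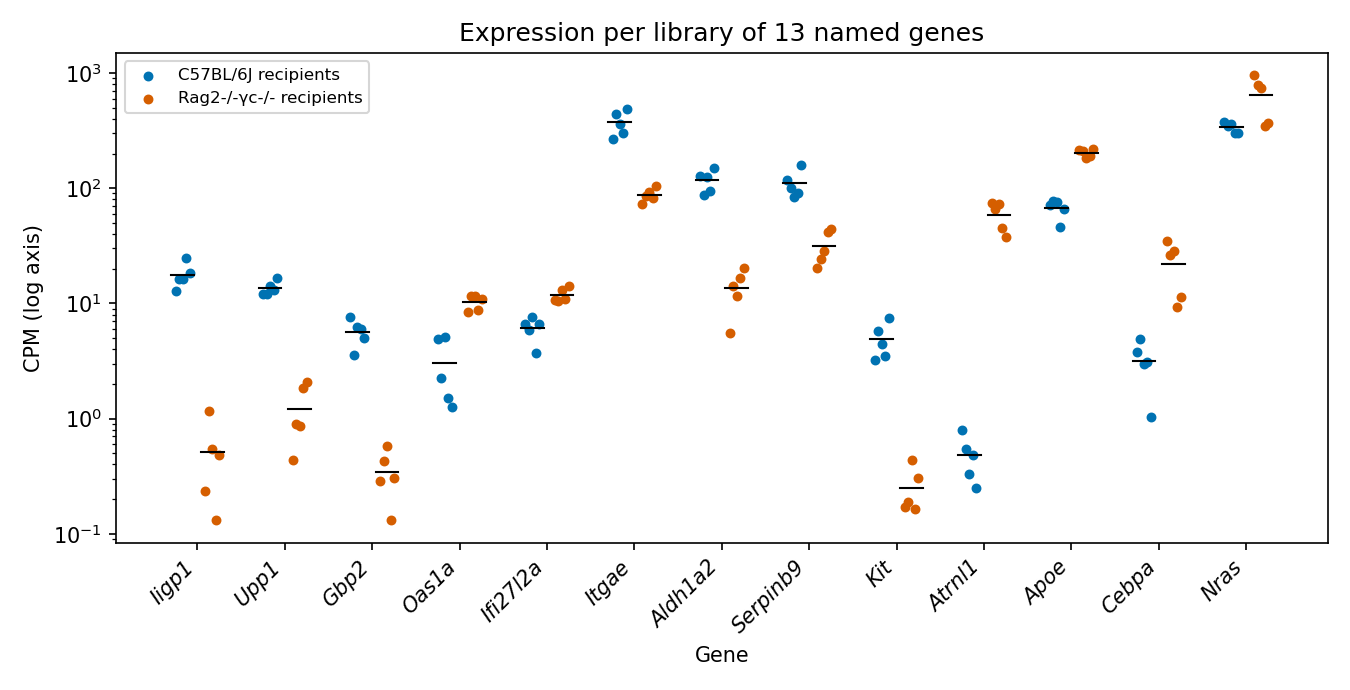
CPM (log axis) of 13 named genes in each of the 10 libraries, one point per library, with black lines at the group means. Iigp1, Upp1 and Gbp2 lie at least 3.58 CPM in the C57BL/6J libraries and at most 2.07 CPM in the Rag2-/-γc-/- libraries, while Nras is at 745 to 956 CPM in Rag2-/-γc-/- libraries 7, 8 and 9 and 301 to 374 CPM in the other 7.

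The gene lists for the 2 kinds of interferon response had opposite directions. Of 33 tested genes of the interferon gamma response, 15 rose and 1 fell in cells from C57BL/6J recipients (22 and 2 when adjusted over the list alone). The list as a whole was higher (camera adjusted p = 1.2e-09; adjusted p = 0.096 with an estimated correlation). Besides Iigp1 and Upp1, the guanylate-binding protein gene Gbp2 rose 16.5-fold, from 0.345 ± 0.167 to 5.70 ± 1.51 CPM, and the GTPase gene Tgtp2 rose 1.76-fold. The log2 fold change of Gbp2 was 4.66 without Rag2-/-γc-/- libraries 7, 8 and 9, against 4.05 with all. Irf1, a transcription factor of the interferon response, rose by 0.68 ± 0.14 on the log2 scale (SE; edgeR adjusted p = 0.0146). Genes of the type I interferon response went the other way: of 36 tested, 10 fell and 1 rose (19 and 2 when adjusted over the list alone). This list was lower as a whole (camera adjusted p = 2.2e-07; adjusted p = 0.52 with an estimated correlation). Oas1a, a sensor of double-stranded RNA, had 3.01 ± 1.88 against 10.3 ± 1.58 CPM, and Ifi27l2a 6.07 ± 1.47 against 11.9 ± 1.66 CPM. Xaf1 fell by 1.14 ± 0.27 on the log2 scale, a call lost without any 1 of 6 libraries (C57BL/6J 1, 3, 5 or 6, Rag2-/-γc-/- 8 or 9; adjusted p up to 0.069). The member that rose was Zbp1, a sensor of Z-form nucleic acids, at 1.78-fold. Without Rag2-/-γc-/- libraries 7, 8 and 9 the medians of these lists were 0.92 and -0.31 (0.68 and -0.86 with all libraries), and Irf1, Oas1a, Ifi27l2a and Xaf1 were no longer past the threshold. Summed T cell markers were higher in the same recipients (107 ± 40.1 against 37.3 ± 10.9 CPM).

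**Figure D3:**
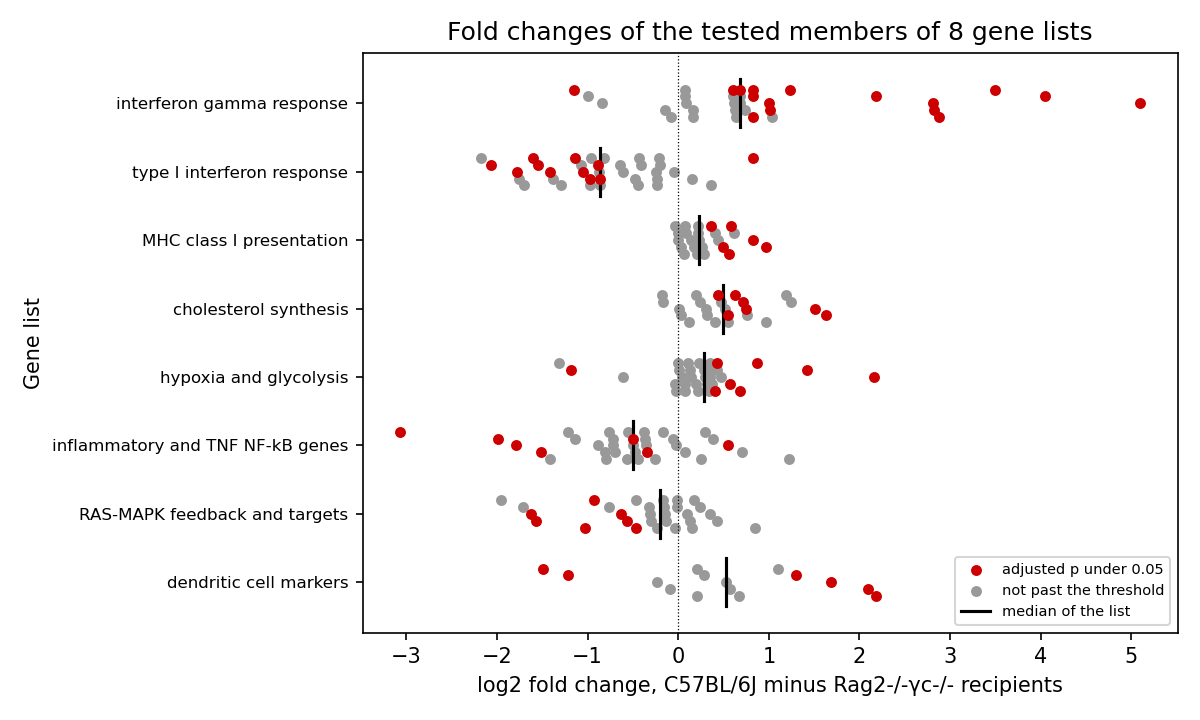
Log2 fold changes (C57BL/6J minus Rag2-/-γc-/- recipients) of the tested members of 8 gene lists fixed before the data were examined, one point per gene, with red points past an edgeR adjusted p of 0.05 and black lines at the list medians. Medians are 0.68 for the interferon gamma response and -0.86 for the type I interferon response.

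Antigen presentation genes were higher in part. Of 24 MHC class I presentation genes 6 rose and none fell (12 and 0 when adjusted over the list alone), and the list was higher as a whole (camera adjusted p = 1e-04; adjusted p = 0.45 with an estimated correlation). H2-Q7, a non-classical class I gene, had 195 ± 35.3 against 99.4 ± 18.7 CPM (SD, n = 5 each; edgeR adjusted p = 0.00338, but 0.1 without Rag2-/-γc-/- libraries 7, 8 and 9). Nlrc5, the class I transactivator, rose 1.78-fold, H2-T23 1.49-fold and the proteasome activator gene Psme1 1.40-fold, each losing its call without C57BL/6J library 6 or Rag2-/-γc-/- library 8 or 9 (adjusted p up to 0.08), and Psme1 also without library 7. B2m and the classical class I genes H2-K1 and H2-D1 were not past the threshold in edgeR. Their log2 fold changes were 0.03 ± 0.14 for B2m, 0.22 ± 0.12 for H2-K1 and -0.04 ± 0.11 for H2-D1 (SE). B2m was at 1370 ± 205 against 1350 ± 222 CPM. H2-K1 passed the threshold in limma-voom with sample quality weights (log2 fold change 0.31, adjusted p = 0.012). The signs for B2m and H2-D1 flipped when single libraries were left out. For MHC class II, 3 of 14 genes rose (4 higher and 1 lower when adjusted over the list alone; camera adjusted p = 0.043; adjusted p = 0.63 with an estimated correlation). H2-DMb2, which encodes a chain of the peptide-exchange chaperone of class II molecules, rose 2.25-fold. The class II transactivator Ciita had 274 ± 43.6 against 155 ± 53.4 CPM, a call lost without any 1 of 7 libraries (all but C57BL/6J 1 and Rag2-/-γc-/- 10 and 11; adjusted p up to 0.098). H2-Eb2 rose 4.27-fold from under 1 CPM, with 4.21 CPM in C57BL/6J library 1 and a log2 fold change of 1.41 without it, and lost its call without C57BL/6J library 6 or Rag2-/-γc-/- library 7, 8, 9 or 11 (adjusted p up to 0.083) and under limma-voom. The class II list lost its own call without C57BL/6J library 3 or 6 or Rag2-/-γc-/- library 10 or 11 (adjusted p up to 0.19). Its adjusted p was 0.63 without both of the last and 0.058 with genes of several lists left out. Summed dendritic cell markers were higher in the same recipients (4220 ± 436 against 3260 ± 263 CPM). The difference in summed B and plasma cell markers was not past the threshold (442 ± 117 against 402 ± 52.4 CPM).

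Single members of the lists of molecules that act on lymphocytes changed, while none of these lists passed the test as a whole. Serpinb9, an inhibitor of granzyme B, had 110 ± 30.4 CPM in C57BL/6J recipients against 31.8 ± 10.6 CPM (SD, n = 5 each), a log2 fold change of 1.80 ± 0.24 (SE; edgeR adjusted p = 0.00134). Its neighbour Serpinb6b rose 2.55-fold, while the cell death genes Bbc3 and Casp8 fell by 0.52 and 0.44 on the log2 scale. In all, 2 rose and 2 fell among 33 genes of resistance to killing and death receptors (3 and 4 when adjusted over the list alone; camera adjusted p = 0.53). Bbc3 lost its call without C57BL/6J library 6 (adjusted p = 0.05), and Casp8 without C57BL/6J library 5 or Rag2-/-γc-/- library 7 or 8 (adjusted p up to 0.055). Among 27 checkpoint and inhibitory ligand genes, 3 rose and 4 fell (8 and 5 when adjusted over the list alone; camera adjusted p = 0.41). Ctla4, an inhibitory receptor gene typical of T cells, rose from 0.254 ± 0.147 to 2.35 ± 0.76 CPM. It had 3.57 CPM in C57BL/6J library 5 and 2.57 CPM in library 1. Zap70, a kinase gene of T cell receptor signalling, had 0.326 and 3.60 CPM in these libraries. The rise of Ctla4 can therefore not be read as T cell RNA alone. Pvrl2 (Nectin2), a ligand of lymphocyte receptors, was 3.62-fold higher in Rag2-/-γc-/- recipients. Fgl2 rose and Lgals9 fell (log2 fold changes 0.78 and -1.66). The call for Fgl2 was lost without any 1 library other than C57BL/6J 1 and Rag2-/-γc-/- 7 and 10 (adjusted p up to 0.086), and that for Lgals9 without C57BL/6J library 3, 5 or 6 or Rag2-/-γc-/- library 7, 8 or 9 (adjusted p up to 0.087). Without libraries 7, 8 and 9 Lgals9 was at -1.04. The median log2 fold change of this list, 0.22, and the direction of camera were opposite in sign to its mean, -0.02. Cd274, which encodes the checkpoint ligand PD-L1, had 6.43 ± 1.80 against 12.8 ± 5.76 CPM and was not past the threshold (edgeR adjusted p = 0.0772). It passed without Rag2-/-γc-/- library 10 (edgeR adjusted p = 0.018) and in DESeq2 (adjusted p = 0.018). Cd274 was at 12.8 to 20.9 CPM in Rag2-/-γc-/- libraries 7, 8 and 9 but at 6.17 and 8.75 CPM in 10 and 11. In the C57BL/6J libraries it was at 3.75 to 8.83 CPM. Without libraries 7, 8 and 9 its log2 fold change was -0.21 (edgeR adjusted p = 0.87).

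The 18 genes of costimulation and adhesion to lymphocytes included 2 that rose and 1 that fell (4 and 4 when adjusted over the list alone; camera adjusted p = 0.81). Cd226 rose 2.13-fold and Slamf7 2.96-fold, both receptors found on lymphocytes and myeloid cells; Il18 was lower at 0.461 ± 0.206 against 1.06 ± 0.276 CPM, a call lost without C57BL/6J library 3, 5 or 6 or Rag2-/-γc-/- library 7, 8, 9 or 11 (adjusted p up to 0.13). The median log2 fold change of this list was 0 and its mean -0.03, while camera's direction was up. The costimulatory ligand genes Cd80 (log2 fold change -0.19 ± 0.20, SE) and Cd86 (0.35 ± 0.12) were not past the threshold (edgeR adjusted p = 0.569 and 0.0982), although Cd86 passed it without C57BL/6J library 1 (adjusted p = 0.014). Of 10 NK cell ligand genes 2 rose and 2 fell (2 and 4 when adjusted over the list alone; camera adjusted p = 0.68). The E-cadherin gene Cdh1 had 47.8 ± 7.98 against 19.3 ± 3.46 CPM (SD, n = 5 each), and Raet1d, a ligand of the activating receptor NKG2D, fell from 1.05 ± 0.0367 to 0.39 ± 0.135 CPM.

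Some genes downstream of RAS and of inflammatory signals were lower in C57BL/6J recipients, and most of the others were not past the threshold. Of 30 genes of RAS-MAPK feedback and targets, 7 fell and none rose (8 and 0 when adjusted over the list alone; camera adjusted p = 0.01; adjusted p = 0.52 with an estimated correlation). The feedback inhibitors Spred1 (65.4 ± 8.09 against 101 ± 8.85 CPM), Spred2 (40.5 ± 3.51 against 59.9 ± 8.19 CPM) and Dusp6 (184 ± 20.6 against 254 ± 26.1 CPM) were among them, and Dusp6 lost its call without C57BL/6J library 6 (adjusted p = 0.055). Spry1, another feedback inhibitor, fell by 1.62 on the log2 scale, at 0.225 ± 0.0756 against 0.702 ± 0.178 CPM. Nras, also a member of this list, was just past the threshold (log2 fold change -0.93 ± 0.26, SE; edgeR adjusted p = 0.0498), with 956, 787 and 745 CPM in Rag2-/-γc-/- libraries 7, 8 and 9 but 348 and 370 CPM in libraries 10 and 11. The C57BL/6J libraries had 301 to 374 CPM. The call was lost without any 1 library other than Rag2-/-γc-/- 10 or 11 (adjusted p up to 0.12), under limma-voom, robust dispersions and 1 surrogate variable. The log2 fold change was -0.09 without libraries 7, 8 and 9. Reads from an endogenous and an introduced Nras were not told apart. Of 35 inflammatory and TNF NF-kB genes 6 fell and 1 rose (7 and 2 when adjusted over the list alone; camera adjusted p = 0.0018; adjusted p = 0.63 with an estimated correlation). The chemokine genes Ccl3 and Ccl4 were 3.98-fold and 3.47-fold higher in Rag2-/-γc-/- recipients at a few CPM, and the transcription factor genes Nfkb1 and Relb fell by 0.34 and 0.50 on the log2 scale. The call for Ccl3 was lost without C57BL/6J library 3 or 5 or Rag2-/-γc-/- library 7, 8 or 9 (adjusted p up to 0.07), that for Nfkb1 without C57BL/6J library 3, 4 or 6 or Rag2-/-γc-/- library 8 or 9 (up to 0.069), and that for Relb without C57BL/6J library 3, 5 or 6 or Rag2-/-γc-/- library 7 (up to 0.073). The list had a camera adjusted p of 0.18 without libraries 7, 8 and 9. None of 28 immediate early and heat shock genes passed the edgeR threshold (0 when adjusted over the list alone; camera adjusted p = 0.53), 7 had an unadjusted p under 0.05, and DESeq2 called 2, limma-voom 0 and limma-voom with sample quality weights 18. Zfp36 had the smallest edgeR adjusted p, 0.0772, and 0.035 without Rag2-/-γc-/- library 10. The TGF-beta pathway had 2 higher and 2 lower genes of 22 (2 and 6 when adjusted over the list alone; camera adjusted p = 0.098, and 0.032 without Rag2-/-γc-/- library 10), among them Pmepa1 and Smad7, which rose 1.65-fold and 2.78-fold, and Tgfbr2, which fell by 0.53 on the log2 scale. Tgfbr2 lost its call without C57BL/6J library 5 or Rag2-/-γc-/- library 7 or 9 (adjusted p up to 0.059), and the log2 fold change of Smad7 was 2.10 without libraries 7, 8 and 9, against 1.47 with all. Among 24 p53 targets, Ccng1 was higher, and Bbc3 and Trp53inp1 were lower (3 and 5 when adjusted over the list alone; camera adjusted p = 0.72). Trp53inp1 was at 103 to 150 CPM in Rag2-/-γc-/- libraries 7, 8 and 9 and at 6.11 and 6.68 CPM in libraries 10 and 11, against 6.68 to 13.3 CPM in the C57BL/6J libraries, and its log2 fold change turned from -2.90 to 0.64 without libraries 7, 8 and 9. Ccng1 lost its call without C57BL/6J library 1, 3 or 6 or Rag2-/-γc-/- library 7, 8 or 9 (adjusted p up to 0.096), and Trp53inp1 without any 1 library other than Rag2-/-γc-/- 10 or 11 (up to 0.11), under limma-voom and with 1 surrogate variable.

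Metabolic lists were mostly higher in C57BL/6J recipients. Cholesterol synthesis had 7 higher genes of 24 and none lower (10 and 0 when adjusted over the list alone; camera adjusted p = 6.5e-05; adjusted p = 0.52 with an estimated correlation). Fdps, an enzyme of the mevalonate pathway, had 62.2 ± 23 against 20.1 ± 7.26 CPM (SD, n = 5 each), and the squalene epoxidase gene Sqle 47.0 ± 17 against 16.6 ± 8.26 CPM. Mvd and Hmgcs1 rose 1.68-fold and 1.46-fold; Sqle lost its call without Rag2-/-γc-/- library 9 (adjusted p = 0.053), Mvd without C57BL/6J library 6 or Rag2-/-γc-/- library 8 or 9 (adjusted p up to 0.057) and Hmgcs1 without C57BL/6J library 1, 5 or 6 or Rag2-/-γc-/- library 7, 8, 9 or 11 (adjusted p up to 0.1). Of 33 hypoxia and glycolysis genes 7 rose and 1 fell (12 and 2 when adjusted over the list alone; camera adjusted p = 0.00011; adjusted p = 0.42 with an estimated correlation). The aldolase gene Aldoc rose 1.82-fold, the collagen prolyl hydroxylase gene P4ha2 4.47-fold and the mitophagy receptor gene Bnip3 1.61-fold, while the glucose transporter gene Slc2a3 was 2.26-fold higher in Rag2-/-γc-/- recipients. In oxidative phosphorylation Cycs (1.71-fold) alone passed the threshold among 39 genes (1 when adjusted over the list alone; camera adjusted p = 0.03; adjusted p = 0.73 with an estimated correlation), and the list lost its call without C57BL/6J library 1 or 6 or Rag2-/-γc-/- library 11 (adjusted p up to 0.68), without both Rag2-/-γc-/- libraries 10 and 11 (0.32), and under the stricter filter of at least 1 CPM in 5 libraries (0.052). Cycs lost its call without C57BL/6J library 6 or Rag2-/-γc-/- library 7, 8 or 9 (adjusted p up to 0.071). The cell cycle list shifted up by a median log2 fold change of 0.34 (camera adjusted p = 8.3e-05; adjusted p = 0.63 with an estimated correlation), although Ccne1 (1.42-fold) was the 1 gene of 40 past the threshold (0 when adjusted over the list alone). No gene of 29 Myc targets and nucleolar genes passed it in edgeR, where 3 had an unadjusted p under 0.05, while DESeq2 called 2, limma-voom 0 and limma-voom with sample quality weights 16 (0 when adjusted over the list alone; camera adjusted p = 0.003; adjusted p = 0.63 with an estimated correlation), with Ddx21 closest at 253 ± 16.4 against 207 ± 22.6 CPM (edgeR adjusted p = 0.078, and 0.03 without Rag2-/-γc-/- library 11). The median log2 fold changes of the cell cycle and Myc lists turned from 0.34 and 0.26 to -0.09 and -0.06 without Rag2-/-γc-/- libraries 7, 8 and 9. Ccne1 lost its call without C57BL/6J library 3, 5 or 6 or Rag2-/-γc-/- library 7, 8 or 9 (adjusted p up to 0.079).

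Stem, granulocytic and monocytic lists held both called and uncalled genes. Of 16 stem and progenitor genes 4 rose and 2 fell (4 and 2 when adjusted over the list alone; camera adjusted p = 0.68). The receptor tyrosine kinase gene Kit rose 19.7-fold from 0.252 ± 0.117 to 4.88 ± 1.77 CPM (edgeR adjusted p = 7.19e-05), Ly6a, which encodes Sca-1, 2-fold and Myb 7.26-fold from under 0.12 CPM, whereas Cd34 fell from 336 ± 120 to 129 ± 26.3 CPM (SD, n = 5 each). The median log2 fold change of this list, -0.2, was opposite in sign to its mean, 0.23, and to camera's direction, and fry called the list higher (adjusted p = 0.01). The granulocytic list shifted down (camera adjusted p = 0.012; adjusted p = 0.63 with an estimated correlation), with 1 of 20 genes lower and none higher (2 and 0 when adjusted over the list alone), and lost its call without Rag2-/-γc-/- library 11 (adjusted p = 0.053) and without libraries 7, 8 and 9 (0.59). The gene was Cebpa, a transcription factor of myeloid differentiation, 6.98-fold higher in Rag2-/-γc-/- recipients. The groups overlapped in the mean log2 CPM of the granulocytic list, centred per gene. It was -0.94 to 1.04 in the C57BL/6J libraries and -0.82 to 1.13 in the Rag2-/-γc-/- libraries. Fry did not call the list (adjusted p = 0.23). Without libraries 7, 8 and 9 the log2 fold changes of Cd34 and Cebpa were -0.73 and -1.71, neither past the threshold. Among 36 monocyte and macrophage genes 5 fell and 1 rose (8 and 3 when adjusted over the list alone; camera adjusted p = 0.1, but 0.039 to 0.049 without C57BL/6J library 1 or 4 or Rag2-/-γc-/- library 7 or 10). Apoe fell from 203 ± 16.5 to 67.6 ± 12.8 CPM (log2 fold change -1.59 ± 0.14, SE; edgeR adjusted p = 8.62e-05), the haem oxygenase gene Hmox1 from 767 ± 205 to 390 ± 109 CPM and the iron exporter gene Slc40a1 from 75.3 ± 26.6 to 22.5 ± 12.6 CPM, while the lysozyme gene Lyz1 rose 2.49-fold. Slc40a1 lost its call without C57BL/6J library 3, 4 or 5 or Rag2-/-γc-/- library 8 (adjusted p up to 0.068).

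The summed level of dendritic cell markers was higher in C57BL/6J recipients, at 4220 ± 436 against 3260 ± 263 CPM (SD, n = 5 each; exact permutation test, two-sided, p = 0.0079, adjusted p = 0.016). Wdfy4 made up 2090 of the 4220 CPM, and over all libraries 7 of the 18 matched markers averaged over 50 CPM and 3 under 1 CPM. Of 15 tested genes 4 rose and 2 fell (8 and 2 when adjusted over the list alone; camera adjusted p = 0.014; adjusted p = 0.45 with an estimated correlation). Itgae, the integrin chain CD103, rose 4.25-fold to 373 ± 92.2 CPM (log2 fold change 2.09 ± 0.17, SE; edgeR adjusted p = 7.19e-05). The cytokine receptor gene Flt3 rose 4.52-fold, with 50.2 CPM in C57BL/6J library 6 against 10.8 to 20.5 CPM in the other 4 and a log2 fold change of 1.58 without that library. The transcription factor genes Irf4 and Tcf4 were 2.33-fold and 2.81-fold higher in Rag2-/-γc-/- recipients. Without Rag2-/-γc-/- libraries 7, 8 and 9, Flt3, Irf4 and Tcf4 were not past the threshold and the list had a camera adjusted p of 0.099. Without libraries 10 and 11 that p was 0.052.

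Markers of lymphocytes were measured because the recipients differ in the lymphocytes they hold. Summed T cell markers were at 107 ± 40.1 CPM in C57BL/6J recipients and 37.3 ± 10.9 CPM in Rag2-/-γc-/- recipients, and summed NK and cytotoxic markers at 41.3 ± 4.61 and 20.9 ± 8.10 CPM (SD, n = 5 each; exact permutation tests, two-sided, adjusted p = 0.016 each). The T cell call was lost without Rag2-/-γc-/- libraries 10 and 11 (difference 76.6 CPM, exact permutation adjusted p = 0.086). The difference was then larger than the 69.3 CPM with all libraries, and the sums stayed apart (74.3 to 165 against 23.2 to 34.2 CPM). Besides there being fewer assignments, the high sums of C57BL/6J libraries 1 and 6 (165 and 132 CPM) let other assignments reach as large a difference. Cd8a, which is also a dendritic cell marker, made up 71.0 of the 107 CPM in C57BL/6J recipients and 28.9 of the 37.3 CPM in Rag2-/-γc-/- recipients. Of the NK and cytotoxic sums, Klrd1 and Klrk1 made up 18.3 and 14.1 CPM in C57BL/6J recipients. They made up 12.9 and 5.05 CPM in Rag2-/-γc-/- recipients, which lack NK cells, so most of this sum cannot be read as NK cell content. Among T cell markers other than Cd8a, 223 summed counts of Zap70, a kinase of T cell receptor signalling, faced 3 in the Rag2-/-γc-/- group, a ratio of 74.6 (95% counting interval 25.2 to 364). For Icos 392 counts faced 3, a ratio of 131 (44.5 to 638). Icos did not follow Zap70 in C57BL/6J libraries 1 and 6, which had 3.60 and 0.503 CPM of Zap70 but 1.99 and 4.58 CPM of Icos. The rise of Icos can therefore not be read as T cell RNA alone. The ratio of Zap70 was 42.1 (14 to 207) without C57BL/6J library 1 and 157 (28 to 6240) without Rag2-/-γc-/- library 7. The cytotoxic granule gene Nkg7 and the antibody light chain gene Igkc had no counts in any Rag2-/-γc-/- library and were at least 61.5-fold and 585-fold higher in C57BL/6J recipients, against a floor of 3 counts over the group. Without C57BL/6J library 1 these bounds were 39.2-fold and 375-fold. Igkc reached 24.8 CPM in C57BL/6J library 1 and 1.22 CPM in library 4. Il2rb rose 46.8-fold to 2.31 ± 2.11 CPM and Klrk1, which encodes NKG2D, 2.80-fold to 14.1 ± 3.90 CPM. Of the tested genes 3 of 11 T cell markers, 3 of 5 NK markers and 5 of 15 B and plasma cell markers rose, and 1 B cell marker, Cd22, fell from 43.7 ± 4.38 to 13 ± 9.62 CPM. Adjusted over the list alone, 8, 4 and 9 rose and 1 of each list fell. Camera adjusted p was 0.00095, 0.0032 and 0.00058 (adjusted p = 0.52, 0.42 and 0.45 with an estimated correlation), and the T cell list lost its call under the stricter filter of at least 1 CPM in 5 libraries (adjusted p = 0.35). 2010001M09Rik (Mzb1) and AC160982.1 (Igha), plasma cell genes, rose as well, the first 3.63-fold and the second from 2 to 579 summed counts (ratio 290, counting interval 80.0 to 2400). The ratio of AC160982.1 was 184 (50.5 to 1530) without C57BL/6J library 3, and without Rag2-/-γc-/- library 8, which held both counts of its group, the gene was at least 153-fold higher. The difference in summed B and plasma cell markers was not past the threshold (442 ± 117 against 402 ± 52.4 CPM; exact permutation test, adjusted p = 0.68), and the difference turned from 39.1 to -11.6 CPM without C57BL/6J library 1. As a mean of log2(CPM + 1) these markers were higher by 0.86 (exact permutation test, adjusted p = 0.013). In Rag2-/-γc-/- recipients, which lack B cells, most of the sum was Xbp1 (209 CPM), Ighm (100 CPM), Cd22 (43.7 CPM) and Bank1 (42.9 CPM). The sum and the fall of Cd22 can therefore not be read as B cell content. C57BL/6J library 1 had the highest T and B cell sums, 165 and 644 CPM, and without it the log2 fold change of Il2rb was 4.88, against 5.55 with it. Leaving out Rag2-/-γc-/- library 11 moved Il2rb to 6.33, leaving out 10 and 11 to 6.43 and leaving out 7, 8 and 9 to 4.73. The log2 fold change of Klrk1 was 2.22 without 7, 8 and 9, against 1.49 with all.

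Markers of other cells were lower or mixed. Of 18 erythroid genes 3 fell and none rose (11 lower and 1 higher when adjusted over the list alone; camera adjusted p = 0.00091; adjusted p = 0.45 with an estimated correlation), namely Tmod1, Spnb1 (Sptb) and Epor, at 30.8-fold, 3.11-fold and 3.36-fold higher in Rag2-/-γc-/- recipients. Epor lost its call without C57BL/6J library 3, 4, 5 or 6 or Rag2-/-γc-/- library 8 or 9 (adjusted p up to 0.093), and the log2 fold change of Tmod1 was -2.90 without Rag2-/-γc-/- libraries 7, 8 and 9, and -5.53 without 10 and 11, against -4.94 with all. That of Spnb1 was -0.73 without libraries 7, 8 and 9 (edgeR adjusted p = 0.36), against -1.64 with all. The summed erythroid markers were 298 ± 27.8 against 383 ± 61.7 CPM (exact permutation test, two-sided, adjusted p = 0.051). This p was 0.038 without C57BL/6J library 1 or Rag2-/-γc-/- library 7 or 10 and 0.021 as a mean of log2(CPM + 1). Of the summed erythroid markers, Tspan33 made up 85.8 against 89.3 CPM and Tfrc 77.9 against 51.8 CPM. The haemoglobin genes Hbb-b1 and Hba-a2 made up 21.4 against 59.3 CPM and 17.1 against 56.7 CPM. Of 10 megakaryocyte and platelet genes 3 rose, Clec1b (2.82-fold), Itga2b (3.52-fold) and F2rl2 (2.71-fold), and none fell (3 and 0 when adjusted over the list alone; camera adjusted p = 0.44), with sums of 632 ± 43.1 and 641 ± 68.6 CPM (adjusted p = 0.77). Plek made up 384 and 431 CPM of these sums, and Nbeal2 151 and 140 CPM. Without libraries 7, 8 and 9 the log2 fold change of F2rl2 was 2.21, against 1.44 with all. This list's median log2 fold change, -0.11, had the sign opposite to its mean, 0.04, and to its camera direction. Among 8 mast cell, basophil and eosinophil genes Kit rose and Fcer1a and Hdc fell (2 and 4 when adjusted over the list alone; camera adjusted p = 0.89), with sums of 92.0 ± 12.6 and 80.9 ± 5.44 CPM (adjusted p = 0.16). Fcer1a had a log2 fold change of -3.85 without C57BL/6J library 5, against -2.70, and Hdc lost its call without C57BL/6J library 1, 4, 5 or 6 or Rag2-/-γc-/- library 7, 8 or 9 (adjusted p up to 0.076) and under limma-voom. The log2 fold change of Hdc was -0.33 without libraries 7, 8 and 9 (edgeR adjusted p = 0.86) and -3.02 without 10 and 11, against -2.43 with all. Camera put this list lower and fry higher, neither past the threshold. Siglec5 made up 77.2 of the 92.0 CPM in C57BL/6J recipients and 66.3 of the 80.9 CPM in Rag2-/-γc-/- recipients. Stroma and endothelium markers summed to 356 ± 25.2 against 572 ± 53.6 CPM (exact permutation test, two-sided, adjusted p = 0.016), most of it Col4a1 (297 ± 55.7 against 517 ± 56.9 CPM). In that list Col4a1 and Pecam1 fell and Col1a1 rose among 8 tested genes (2 and 2 when adjusted over the list alone; camera adjusted p = 0.46). Rag2 and Il2rg, the genes disrupted in the immunodeficient recipients but not stated to be so in the leukaemia, had 2.07 ± 0.344 against 4.53 ± 2.11 CPM (edgeR adjusted p = 0.0576) and 13.2 ± 2.95 against 11.1 ± 0.559 CPM (edgeR adjusted p = 0.302). Runx1 had 53.1 ± 5.18 against 45.2 ± 12.6 CPM (edgeR adjusted p = 0.381). Rag2 passed the threshold without Rag2-/-γc-/- library 10 or 11 (edgeR adjusted p = 0.022 and 0.017), and Runx1 without library 11 (0.042). Rag2 also passed it in DESeq2 (log2 fold change -1.14, adjusted p = 0.0098). In limma-voom with sample quality weights both Rag2 (-1.46, adjusted p = 0.00095) and Runx1 (0.52, adjusted p = 0.0029) passed. Rag2 was at 5.68 to 6.58 CPM in Rag2-/-γc-/- libraries 7, 8 and 9 and at 1.52 to 2.52 CPM in all other libraries. The log2 fold changes of Rag2 and Runx1 were -0.12 and -0.06 without libraries 7, 8 and 9 (edgeR adjusted p = 0.92 and 0.93). Xist, the 1 tested sex gene, had 1090 ± 592 against 1460 ± 105 CPM (edgeR adjusted p = 0.612), with 82.8 CPM in C57BL/6J library 1. Values of near-identical family members, such as the H2-Q, H2-T, Gbp, Tgtp, Oas1, Serpinb, Raet1 and Ly6 genes, are uncertain to the extent that the authors' counting divided shared reads between them.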

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

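The test of Y-linked genes and the comparison of T cell receptor genes per library were chosen after the results were seen. In 263 groups of 5 values (library measures, sums of cell type markers and named genes), 22 held a library that stood apart. Its gap to the nearest of the others exceeded 0.71 of the whole range. Independent, normally distributed values would give about 1 in 20 such groups (13.2 expected). CPM values of genes with few counts are not so distributed, and some groups share genes. The 22 therefore do not show an excess over chance. Of the 22, 7 were in C57BL/6J library 1 and 4 in C57BL/6J library 6. Library 1 stood apart for the summed B and plasma cell markers (644 CPM, next 423), the summed erythroid markers (347 CPM, next 291), H2-Eb2 (4.21 CPM, next 1.64), Cd22 (30 CPM, next 10.6), Myb (0.733 CPM, next 0.428), Fgl2 (375 CPM, next 664) and Itga2b (4.25 CPM, next 7.92). Library 6 stood apart for Gnb4 (19.9 CPM, next 14.4), Fndc5 (29 CPM, next 8.74), Flt3 (50.2 CPM, next 20.5) and Alox5 (0.855 CPM, next 6.44). In the other C57BL/6J libraries, library 5 had the far value for Prss16 (6.44 CPM, next 1.65) and Fcer1a (0.37 CPM, next 0.0611) and library 4 for Xaf1 (8.22 CPM, next 4.22). In the Rag2-/-γc-/- group, library 7 had the far value for Ccl3 (8.75 CPM, next 5.03), Zfp36 (411 CPM, next 229) and Hmox1 (1120 CPM, next 732), library 10 for Nlrp14 (43.5 CPM, next 11.5) and Fdps (33.0 CPM, next 17.8), library 11 for Il2rb (0.126 CPM, next 0.0362) and Runx1t1 (0.0253 CPM, with 0 in the other 4), and library 8 for AC160982.1 (0.0473 CPM, with 0 in the other 4).

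Xist, the RNA that coats the inactive X chromosome, was at 82.8 CPM in C57BL/6J library 1, 6.2% of the mean of the other 4 C57BL/6J libraries, although its gap was not among the 22. Male cells are argued against by the Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty, which had 0 CPM in library 1. Poor recovery of long non-coding RNA is argued against by 106 other such genes, whose median log2 ratio to the other 4 libraries was -0.30 (95% bootstrap interval -0.48 to -0.13), against -4.02 for Xist. Loss of the inactive X may still account for it and stays open: 9 genes known to escape X inactivation had a median log2 ratio 0.12 lower than 316 other X-linked genes (difference -0.12), between the limits set for either answer. The design names no biological explanation for a single library.

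The position of Rag2-/-γc-/- libraries 10 and 11 on the first principal component, away from 7, 8 and 9, is unlikely to come from sequencing depth: after thinning all libraries to 28157719 counts the gap was 1.03 times its size before. Between these libraries 42 genes with a mean of at least 1 CPM differed by over 4 times in every pair, 32 of them higher in 7, 8 and 9. RNA of other cell types cannot be told apart from a change within the leukaemia here: 2 of the 42 genes (4.76%), Hdc and Tmod1, are in the lists of other cell types, between the limits of 2% and 5% set in advance. Both groups of libraries came from the same kind of recipient, so a difference between primary leukaemias stays among the open explanations, untested because the labels name no donors.

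The rise of interferon gamma response genes in C57BL/6J recipients could in principle be RNA of host lymphocytes in the sorted cells, which were gated on GFP. The 15 genes called higher had a median log2 ratio of 0.11 between C57BL/6J libraries 1 and 4, whose summed T cell markers differed by 1.15 on the log2 scale (165 and 74.3 CPM), but the 95% bootstrap interval of -0.24 to 0.51 passes the limit of 0.5 set in advance and the test sets 1 library against 1, so lymphocyte RNA cannot be told apart from a change within the leukaemia by it. The summed T cell receptor and signalling genes were 41.7, 12.4, 4.26, 1.76 and 7.09 CPM in C57BL/6J libraries 1, 3, 4, 5 and 6. In the Rag2-/-γc-/- libraries they were 0.882 to 1.23 CPM. The mean log2 CPM of the 15 genes was 4.18, 3.95, 3.98, 4.03 and 4.03 in these C57BL/6J libraries and 1.90 to 2.38 in the Rag2-/-γc-/- libraries. Over all 33 tested members, called or not, the mean log2 CPM centred per gene was 0.34 to 0.59 against -0.86 to -0.16. Such even levels argue against T cell RNA as the main source of the rise in these genes as a set. They do not cover single genes or RNA of other lymphocytes. Exposure of the leukaemia to interferon gamma in immunocompetent recipients is a hypothesis that these values leave open; it was not tested.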

How the results depend on the processing

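Leaving out libraries 10 and 11, or 7, 8 and 9, of the Rag2-/-γc-/- group was chosen after the data were examined; all other alternatives were planned. Against 464 higher and 624 lower genes, RLE and upper quartile scaling, limma-voom, robust dispersions, 1 surrogate variable and both other count filters stayed within 1.5 times. DESeq2 called 803 and 1155 genes, limma-voom with sample quality weights 3306 and 3217 (weights 0.26 to 3.53), and the test against a 1.5-fold change 126 and 119. The lowest weights were those of C57BL/6J library 1 (0.26) and Rag2-/-γc-/- libraries 10 and 11 (0.30 and 0.34). Calls gained with these weights are therefore not independent of leaving out libraries 10 and 11. Leaving out 1 library gave 275 to 1076 higher and 304 to 1323 lower genes. Without libraries 10 and 11 there were 2786 and 2518, without 7, 8 and 9 there were 148 and 127, where fewer libraries also limit the test. Higher genes made up 42.1 to 43.8% of calls under the 3 scalings. Of 29 lists, 17 were called; camera with an estimated correlation called 0, fry 9 (stem and progenitor genes among them), and the other alternatives 14 to 18. MHC class II lost its call with genes of several lists left out, and T cell markers and oxidative phosphorylation with the stricter filter. Without 7, 8 and 9, checkpoint, immediate early and megakaryocyte lists gained a call (adjusted p = 0.0088, 0.013 and 0.0051). The 4 called sums of other cell types became 3 to 6, the 6 being under mean log2(CPM + 1), which added B and plasma cell (0.86, exact permutation adjusted p = 0.013) and erythroid markers (-0.592, 0.021), and were not computed without 7, 8 and 9. T cell markers missed the threshold without libraries 10 and 11 (76.6 CPM, exact permutation adjusted p = 0.086). There the high sums of C57BL/6J libraries 1 and 6 let other assignments reach as large a difference.

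Results that turned direction were mostly near 0, and the cause was not tested. Leaving out 1 library gave log2 fold changes of -0.08 to 0.03 for H2-D1 and -0.04 to 0.11 for B2m, summed differences of -11.6 to 61.7 CPM for B and plasma cell markers and -28.2 to 11.8 CPM for megakaryocyte markers, and medians of -0.41 to -0.23 for mast cell and -0.26 to -0.05 for immediate early genes, where the test's direction turned. Without libraries 10 and 11, B2m was at -0.12, and the immediate early and megakaryocyte medians were -0.05 and -0.31. Without libraries 7, 8 and 9, Trp53inp1 was at 0.64, Runx1 at -0.06 and H2-D1 at 0.14, and the medians were 0.04 for resistance to killing, -0.09 for the cell cycle, 0.09 for p53 targets, -0.06 for Myc targets and -0.09 for mast cell markers. The mast cell median was 0.21 under the stricter filter, and -0.27 under fry, which gave the opposite direction to camera. With genes of several lists left out, p53 targets were at -0.06 and stem and progenitor genes at -0.23. As a mean of log2(CPM + 1), the differences were 0.0861 for megakaryocyte and -0.00976 for mast cell markers, and on plain library totals megakaryocyte markers differed by 2.39 CPM. In all, 275 of 2671 alternative values of named genes lost the threshold, 24 gained it and 11 turned. The test against a 1.5-fold change made up 61 of the losses, and leaving out libraries 7, 8 and 9 made up 72, besides Trp53inp1, which turned. They also included Nras, Trp53inp1, Hdc and H2-Eb2 under limma-voom, and Il18 under upper quartile scaling and with no filter. Depth limits genes under about 1 CPM, and the lymphocyte genes rest on few counts in the Rag2-/-γc-/- libraries. No paired analysis was possible because the groups share no replicate numbers.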

Other observations

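The genes named outside the rule, and which of the limits decides the test of the Nras region, were chosen after the results were seen; the tests themselves were not. A set of genes separated Rag2-/-γc-/- libraries 7, 8 and 9 from all others. Pik3ip1, an inhibitor of PI3 kinase, was at 74.4 to 92.7 CPM in these 3 libraries, at 1.96 and 11.5 CPM in libraries 10 and 11, and at 11.2 to 33.7 CPM in the C57BL/6J libraries. Klf9 was at 5.25 to 11.4 CPM against 0.152 to 0.531 CPM in the other 7, and the mTOR-binding protein gene Deptor at 15.8 to 21.2 against 0.78 to 2.73 CPM. The cold-inducible Cirbp was at 96.5 to 107 against 17.6 to 38.2 CPM. In the opposite direction, the heat shock gene Hsph1 was at 38.8 to 57.3 CPM against 145 to 399 CPM, and Hspa1b at 41.6 to 125 against 274 to 1110 CPM.

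Nras was 745 to 956 CPM in Rag2-/-γc-/- libraries 7, 8 and 9. A gain of the whole region on chromosome 3 (100938860 to 103912247, GRCm38) is argued against as the whole cause. Between these libraries and 10 and 11, the 20 nearest tested genes differed by a median of 0.06 on the log2 scale (SD 0.56, range -1.01 to 1.01), each by less than the 1.21 of Nras. The 95% bootstrap interval of the median, -0.17 to 0.50, lies below the 0.60 that such a gain was set in advance to need, although it passes the stricter limit set for excluding one. A change of a shorter segment, of Nras alone or of an introduced copy stays open and was not tested.

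Called genes lay next to each other more often than random draws. Of the tested genes in chromosome order, 102 neighbouring pairs were called in the same direction, against a median of 43 (31 to 56 in the middle 95%) in 10000 random draws (permutation p = 1e-04, the smallest that the draws can give). In 20 of these pairs the annotated genes overlap, so shared reads may add to the count. Runs of at least 3 included Serpinb6b, Serpinb9 and Serpinb1b on chromosome 13 (32965209 to 33094380, median log2 fold change 1.35), Ifit2, Ifit3 and Gm14446 on chromosome 19 (34550694 to 34601968, median -2.06), and Dyrk1a, Erg and Ets2 on chromosome 16 (94570010 to 95721051, median -1.27). The longest had 4 genes, Tusc1, Gm12655, 5830433M19Rik and Plaa on chromosome 4 (93334148 to 94603244, median 2.17). Families of related genes that respond together could give such runs as well as changes of a chromosome segment, and the count of 102 does not tell them apart.

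A chance split of 10 independent libraries is argued against for the counts of genes. The splits treat the libraries as exchangeable, so they cannot tell recipient type from primary leukaemias or other unlabelled differences that run with it. In 100 splits of the 10 libraries into 5 and 5, the real one included, only 1, the real split, called as many genes in total (1088, highest other 3), as many in one direction as were higher (464, highest other 3; 1 split), and as many as were lower (624, highest other 3; 1 split). For the gene lists 2 of the 100 splits called as many: the real one with 17 and another with 17, which exchanged C57BL/6J library 4 for Rag2-/-γc-/- library 8. That split called 0 genes in edgeR, as did 3 others with 15, 15 and 16 lists, which also exchanged 1 C57BL/6J library for 1 of the other group. These splits keep most of the real grouping, so their list calls may still reflect it. A more mixed split, with C57BL/6J libraries 1, 3 and 4 and Rag2-/-γc-/- libraries 7 and 8 on the same side, called 13 lists and 0 genes. A high number of lists called by camera with the preset correlation is thus not particular to the real split.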
